A study of Mus musculus with 10 samples.

How the data were processed

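RNA of interscapular brown adipose tissue from 5 control mice (22 °C) and 5 cold-exposed mice (4 °C, 3 days) was sequenced after poly-A selection of 4 µg of total RNA per library, per the labels' protocols. The labels name 10 separate, single-housed mice. The treatment tag of the cold samples reads as room temperature with 4 °C beside it; titles, source names and the treatment protocol all place these samples in the cold group.

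The deposited count table holds raw counts of reads per RefSeq gene model for each library, per the file headers and the values, which are whole numbers with different totals. Reads were aligned with STAR to mm9 and compared with edgeR, per the submitters' processing notes; the versions, the read counter and the annotation release are not given in the sources used here. The deposited table also gives, for each gene model, the bases over which reads were counted, per the file headers. The authors' own comparison is a second deposited table with a log2 fold change, a log2 CPM, a p-value and an adjusted p-value per gene, per the file headers; its filter and test are not given in the sources used here. Counts were made per gene model and no strand setting is given, so reads of overlapping genes, or of near-identical copies, could not be told apart. Of the 115 genes named by rule, 11 overlap another gene model of the table, 10 of them only on the opposite strand. These include Mb, which overlaps Apol6 by 5393 bases (Apol6 was at 69.5 CPM in control and 31.6 in cold libraries), and Bmp8b, which overlaps Oxct2b by 1753 bases. The overlaps are of whole gene spans, not of the bases counted. Reads were counted over 994 bases of Mb, so most of its overlap was not counted for it. No mitochondrially encoded gene was analysed here.

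Columns of control mice carry no group word in the count table and were matched to the control samples by replicate number; 0 columns of single libraries were left unused. Of the 20295 rows, 27 had a symbol turned into a date or used on more than 1 row and kept their RefSeq identifier as name. Gene symbols and coordinates come from the count table. In all 20295 rows the stated transcript length equals end minus start, so starts count from 0 and were raised by 1 for printing. The reference annotation supplied is of another build, so none of its coordinates were used; 20094 of the identifiers occur in its RefSeq table.

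The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling and filterByExpr, which kept 11229 genes, for cold against control with no covariate. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.166. Log2 CPM for principal components and lists used a prior count of 2. Gene lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 31 lists tested. No replicate pair of a group agreed within sampling noise, as 2 deposits of 1 library would (chi-square per degree of freedom 3.2 to 36.1). Libraries were counted separately because the labels name separate mice.

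Before the data were examined, the design, the alternatives, the 35 lists and the rule for named genes were fixed. The rule takes a panel of 17 genes whatever their result, then the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and cold and control libraries that do not overlap. It then takes up to 4 members per list: the 2 with the smallest p and the 2 with the largest change among those called, or the 2 with the smallest p where none was called. Genes named outside the rule are said to be so, apart from copies and neighbours of named genes (Acot1, Bmp8a, Apol6 and Oxct2b). Some genes that the rule takes are not reported here. The lists cover thermogenic genes, mitochondrial and peroxisomal fatty acid oxidation, de novo lipogenesis, lipid uptake, lipolysis, glycolysis, pyruvate, glycogen, the tricarboxylic acid cycle, oxidative phosphorylation, mitochondrial biogenesis, creatine and calcium cycling, cholesterol, the cell cycle, the unfolded protein response, ATF4 targets, the proteasome, heat shock, the extracellular matrix, angiogenesis, secreted factors, the clock, immediate early genes, the interferon response and markers of 10 other cell types. Further lists (cAMP response, glucocorticoid targets, ketone bodies and the 2 sides of the clock) were made after seeing the data and are used in the closing section. The 2 sides of the clock also enter the Results through the clock score, which is the difference between them.

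The alternatives were RLE, upper quartile and unscaled library sizes; library sizes without the 20 most abundant genes, Ucp1 among them; no filter, or a CPM above 1 in at least 5 libraries; DESeq2 1.42.0; the edgeR exact test; limma-voom with and without sample weights; the replicate number as a block; 1 surrogate variable (sva 3.50.0); a test against a log2 fold change of 1; and leaving out each library in turn. Lists were also tested with an estimated correlation and with fry.

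The method was tested on simulated counts drawn from the real means and library sizes for the comparison of cold with control, with 200 genes changed. Each gene was drawn independently, with the dispersion of the trend over expression and not its own. No simulated library stood apart as a whole, so the rates below may be better than in the real data. On 11261 genes tested, 42.4% of 66 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 100% of 64 changed 4-fold were called with the right sign; 5 of 159 calls were false. At this depth, 4446163 to 6923932 counts per library, changes under 1.5-fold will often be missed.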

Results

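Read counts per gene were obtained from poly-A selected RNA of interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades of the mouse. The tissue came from 10 single-housed male mice of the C57BL/6JBomTac strain, 8 weeks old. The control group was 5 mice at 22 °C and the cold group was 5 mice held at 4 °C for 3 days, with 1 library per mouse. The comparison asks which transcripts of the tissue differ after this cold exposure. The count table held 20295 genes, of which 11229 had enough reads to be tested. Library totals of control replicates 1 to 5 were 4600091, 5113051, 4446163, 5776905 and 4993121 counts. Those of cold replicates 1 to 5 were 5733846, 6282377, 6923932, 5986554 and 5676963 counts. Values are normalised read counts in CPM, the count of a gene relative to the TMM-scaled library total, as mean ± SD over 5 libraries, and log2 fold changes of cold relative to control with their standard errors (SE). Coordinates are those of the mouse build mm9.

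The first principal component of log2 CPM held 40% of the variance and separated every cold library from every control library. The second component held 19.2% and set control replicate 2, at -36.5, apart from the other 4 controls, which lay between 2.3 and 23.7. Cold replicate 5 lay nearest to the control group on the first component, at 6.7, where the other 4 cold libraries lay between 24.2 and 31.7. It also stood apart on the second component, at -23.5 against -0.9 to 6 in the other 4, on the same side as control replicate 2. Both libraries entered every comparison. For the gene lists, called members are also given from the fits that each left out 1 library, where these moved a count by over 1.5 times.

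**Figure D1:**
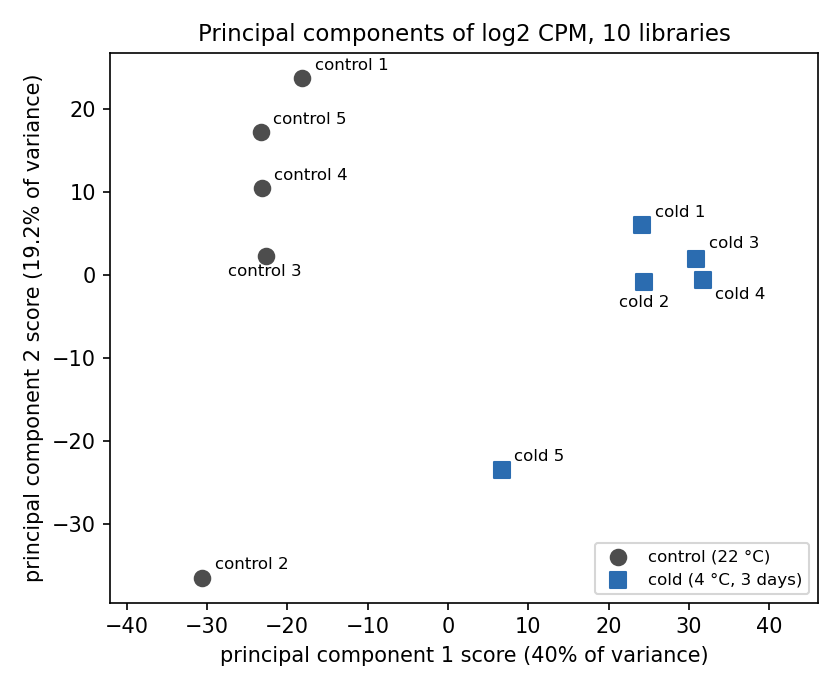
Scores of the 10 libraries on principal components 1 (horizontal, 40% of variance) and 2 (vertical, 19.2%) of log2 CPM; circles are control mice and squares are cold mice. The groups separate along component 1, with cold replicate 5 at 6.7. On component 2 control replicate 2 lies apart from the other controls at -36.5, and cold replicate 5 from the other cold mice at -23.5.

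Several genes of the heat-producing programme were higher after cold exposure, by different amounts. Ucp1, which encodes the uncoupling protein that makes brown fat mitochondria release heat (chromosome 8, 85814247 to 85822355), rose 2.03-fold from 9120 ± 801 to 18500 ± 852 CPM. Elovl3, an elongase of very long chain fatty acids (chromosome 19, 46206389 to 46210184), rose 6.55-fold from 198 ± 55.8 to 1300 ± 323 CPM. The secreted factors Bmp8b (chromosome 4, 122782408 to 122803334) and Fgf21 (chromosome 7, 52869260 to 52870860) rose from low levels, by 4.78 (SE 0.39) and 2.82 (SE 0.42) on the log2 scale. Gyk, a glycerol kinase, rose by 1.05 (SE 0.13). The adjusted p of edgeR's quasi-likelihood test was 1.18e-05 for Ucp1 and Elovl3, 1.11e-05 for Bmp8b, 0.000684 for Fgf21 and 0.000119 for Gyk, and all 5 cold libraries lay above all 5 controls for each. Reads of Bmp8b may be shared with its near-identical neighbour Bmp8a, which was at 0.0826 ± 0.113 CPM in control and 2.62 ± 1.12 CPM in cold libraries.

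Several other fixed members of the panel did not pass the test. Dio2, the deiodinase that activates thyroid hormone, had a log2 fold change of -0.11 (SE 0.51, adjusted p = 0.899), and Ppargc1a, a coactivator of mitochondrial genes, -0.20 (SE 0.58, adjusted p = 0.836). Control replicate 2 held 1500 CPM of Dio2 against 166 to 284 in the other controls. Without it Dio2 was higher in the cold by 0.94 (adjusted p = 0.00285) and Ppargc1a by 1.02 (adjusted p = 0.0159). Cidea, a lipid droplet protein of brown adipocytes, was at 0.07 (SE 0.09) and Prdm16, a regulator of brown fat identity, at -0.09 (SE 0.18). Adrb3, the beta-3 adrenergic receptor, was at -0.63 (SE 0.30, adjusted p = 0.164), and at -0.87 (adjusted p = 0.000649) without control replicate 2. Lep (leptin) was at -0.69 (SE 0.59, adjusted p = 0.441), and at 0.14 without control replicate 1. The glucose transporters Slc2a1 and Slc2a4 were at 0.06 (SE 0.25) and 0.07 (SE 0.11); the estimate for Slc2a1 lay between -0.07 and 0.40 when single libraries were left out. Adipoq, the adipocyte hormone adiponectin, fell by 0.72 (SE 0.15, adjusted p = 0.00519).

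**Figure D2:**
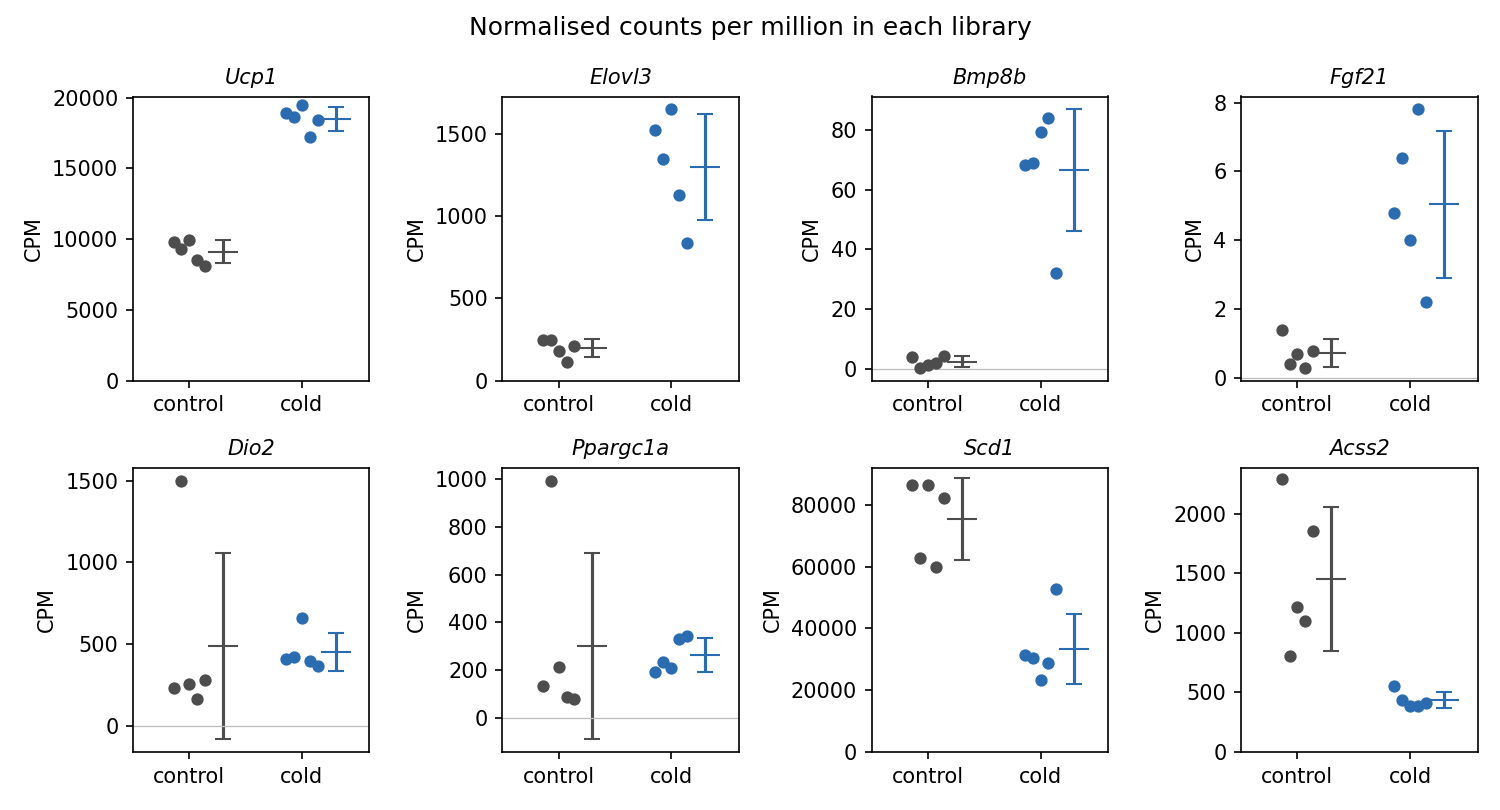
Normalised read counts in CPM (vertical axes, linear) of 8 genes in each library; dots are single mice, and the bar beside them is the mean with its SD over 5 mice. All cold mice lie above all control mice for Ucp1, Elovl3, Bmp8b and Fgf21 and below them for Scd1 and Acss2, while for Dio2 1 control mouse at 1500 CPM lies above every cold mouse.

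Over the whole transcriptome, 1142 genes rose and 1026 fell at an adjusted p under 0.05, together 19.3% of the genes tested. Of these, 239 rose and 159 fell by at least 2-fold. For 1568 genes, 14% of those tested, the 5 cold and 5 control libraries did not overlap, against 0.794% that chance gives. Without cold replicate 5, 374 genes rose by at least 2-fold.

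The largest rises were in genes of varied function. Bdh1, the mitochondrial enzyme that interconverts ketone bodies, went from 0.471 ± 0.38 to 43.7 ± 22.0 CPM (log2 fold change 6.55, SE 0.63). The calcium-dependent membrane binding protein Cpne5 went from 0.354 ± 0.203 to 31.1 ± 17.5 CPM (6.34, SE 0.55). Tacr2, a tachykinin receptor, rose by 4.88, Itih4, an inter-alpha-trypsin inhibitor heavy chain, by 4.67 and Cmah, a sialic acid hydroxylase, by 3.78. The ion channel genes Scn4b and Hcn2 rose by 3.70 (SE 0.36) and 3.66 (SE 0.20), and Arhgef37, a guanine nucleotide exchange factor, by 3.66 (SE 0.49). Without control replicate 1 the value of Arhgef37 was 4.30. Mb, which encodes myoglobin, rose by 3.77 (SE 0.33) from 6.48 ± 4.00 to 89.9 ± 27.5 CPM. The 5 cold libraries lay at 46.2 to 119.3 CPM and the 5 controls at 4.1 to 13.5 CPM. Cold replicates 4 and 5, at 88.9 and 105.9 CPM of Mb, did not hold the high values of the muscle actin Acta1 that are given below. The summed skeletal muscle markers were at 76.0 ± 54.4 CPM in control and 213 ± 228 CPM in cold libraries. The adjusted p of these rises in the quasi-likelihood test lay between 3.25e-07 (Hcn2) and 0.0011 (Itih4). With limma-voom the adjusted p of Itih4 was 0.0892.

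The largest falls were led by Nr4a3, an orphan nuclear receptor, at -4.01 (SE 1, adjusted p = 0.014). Its value was -2.10 (adjusted p = 0.00412) without control replicate 2, and -2.69 (adjusted p = 0.0803) with limma-voom. Vat1l fell from 47.2 ± 13.7 to 4.18 ± 1.09 CPM (-3.50, SE 0.23) and Lctl, a relative of klotho, from 70.5 ± 22.6 to 6.91 ± 1.97 CPM (-3.36, SE 0.26). The abundant transcripts Car3 (carbonic anhydrase) and Apoe (apolipoprotein E) fell by 2.69 and 2.12 on the log2 scale, from 3270 ± 920 and 1470 ± 444 CPM. Pon1 (paraoxonase) fell by 2.26. The non-coding host gene Snhg11 fell by 2.60, Fgf14 fell by 1.99 and Gfra4, a receptor of the GDNF family, fell by 1.98. Apart from Nr4a3, the adjusted p of these falls lay between 1.8e-06 (Vat1l) and 0.00139 (Gfra4).

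**Figure D3:**
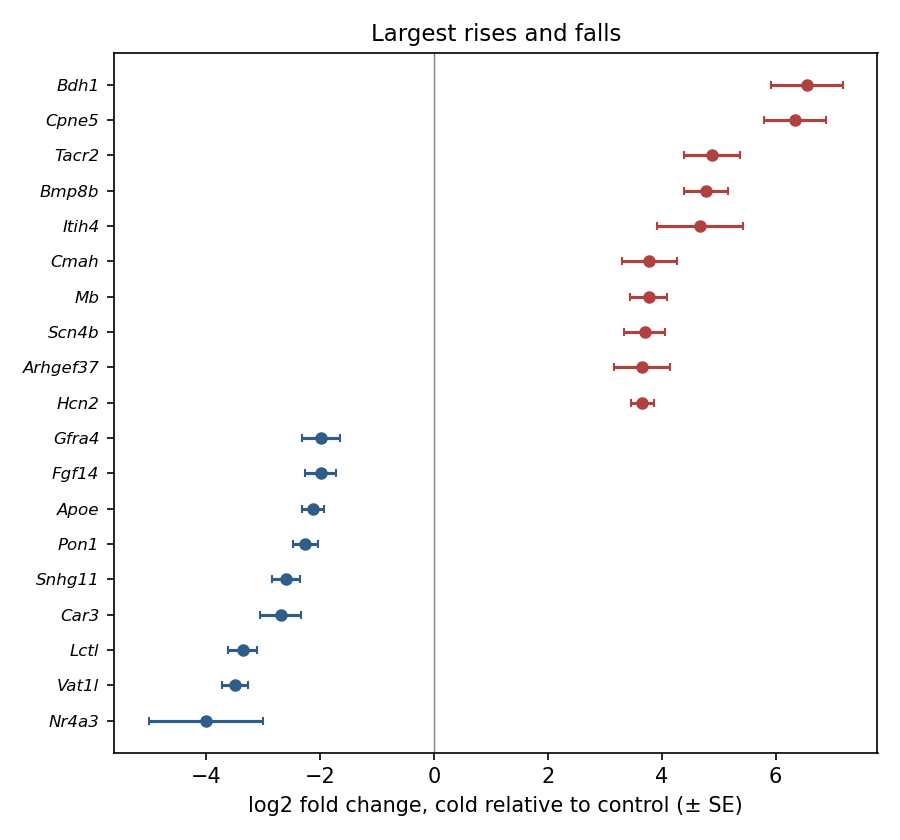
Log2 fold change of cold relative to control (horizontal axis) with SE for the 10 largest rises (red) and 9 of the 10 largest falls (blue) among genes past the threshold whose cold and control libraries do not overlap. The values run from -4.01 (Nr4a3) to 6.55 (Bdh1).

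Of 35 gene lists fixed in advance, 31 had enough measured members for a list test (camera, preset correlation 0.01), and 9 passed it, 6 higher and 3 lower. None of the 9 passed with an estimated correlation in camera, where 1 list had an unadjusted p under 0.05. With fry, a test of each list by itself, 6 lists passed. Of the 9, the de novo lipogenesis (adjusted p = 0.274), cell cycle (0.179), extracellular matrix (0.179), interferon (0.34) and endothelial (0.179) lists did not pass fry. The lipid uptake (0.00325) and the creatine and calcium cycling (0.00445) lists, not among the 9, passed it. Of 100 splits of the 10 libraries into groups of 5, the real one included, 36 gave 9 or more lists by the preset test.

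The thermogenic list had 9 members higher and 3 lower of 30 tested (10 and 3 adjusted over the list alone). Besides the genes named above, Letmd1, a mitochondrial inner membrane protein, rose by 0.57 and Cox7a1, a cytochrome c oxidase subunit, by 0.34, while Cox8b, another subunit, fell by 0.34. These 3 were chosen after their values were seen. This list had an adjusted p of 0.00551, and the adjusted p = 0.261 with an estimated correlation.

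Of 23 tested members of the de novo lipogenesis list, genes of fatty acid synthesis, 5 fell and 0 rose (5 and 0 adjusted over the list alone). Scd1, the stearoyl-CoA desaturase (chromosome 19, 44468940 to 44482199), took 7.43 ± 1.14% of all counts in control and 3.34 ± 0.969% in cold libraries (-1.18, SE 0.20, adjusted p = 0.00152). Acss2, which makes acetyl-CoA from acetate, fell by 1.74 (SE 0.24), Slc25a1, the mitochondrial citrate carrier, by 1.19 and Pnpla3, a lipid acyltransferase and hydrolase, by 1.09. Fasn and Acly, fatty acid synthase and ATP citrate lyase, were at -0.47 (adjusted p = 0.133) and -0.78 (adjusted p = 0.0871). Its camera test gave an adjusted p of 0.02, and the adjusted p = 0.797 with an estimated correlation. It was 0.17 without control replicate 1, 0.0594 without control replicate 5 and 0.065 without cold replicate 4. Control replicate 2 differed from the other controls over this list by a median of -0.94 on the log2 scale. Without it 11 members fell, among them Fasn (-0.62, adjusted p = 0.0174) and Acly (-0.99, adjusted p = 0.00565), and without cold replicate 5 Fasn was at -0.66 (adjusted p = 0.0216).

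Of 24 tested members of the lipid uptake and triglyceride synthesis list, 7 rose and 2 fell (9 and 3 adjusted over the list alone). Fabp3, a fatty acid binding protein, rose by 1.27 (SE 0.14) and Agpat3, an acyltransferase of phospholipid and triglyceride synthesis, by 0.67 (SE 0.07). Angptl4, an inhibitor of lipoprotein lipase, was lower by 0.79 (adjusted p = 0.0405), a call lost in 8 of the 10 fits that left out 1 library, with an adjusted p of up to 0.0866, with limma-voom (0.0542) and without scaling factors (0.0634). With 1 library left out 5 to 8 members rose and 1 to 5 fell, 5 without control replicate 1. This list had an adjusted p of 0.0582 in camera, which was 0.0444 without control replicate 2 and 0.0392 without control replicate 5. It was 0.0465 with the CPM filter and 0.708 with an estimated correlation, and fry gave 0.00325. In the lipolysis and lipid droplet list 1 of 23 members rose and 1 fell, as they did adjusted over the list alone. With 1 library left out 1 to 2 rose and 0 to 4 fell, 4 without control replicate 2 or cold replicate 5, and 7 fell without both. Mgll, the monoacylglycerol lipase, rose by 0.74 (SE 0.12, adjusted p = 0.00139). This list's adjusted p was 0.864.

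Of 24 genes of fatty acid oxidation in mitochondria, 5 rose and 4 fell (7 and 4 adjusted over the list alone), led by Acsl5, an acyl-CoA synthetase, at 1.30 (SE 0.11, adjusted p = 1.18e-05). Slc25a20, the carnitine carrier, rose by 0.56 (SE 0.08) and the thioesterase Acot2 by 0.73 (SE 0.14). Reads of Acot2 may be shared with Acot1, whose log2 fold change was 0.85. In peroxisomes 5 of 23 members rose and 3 fell (7 and 6 adjusted over the list alone). Slc25a17, a peroxisomal cofactor carrier, rose by 1.05 (SE 0.12) and Hsd17b4, an enzyme of peroxisomal beta-oxidation, by 0.38, whereas Abcd2, a peroxisomal fatty acid transporter, fell by 1.44 (SE 0.34). The adjusted p of the lists was 0.283 and 0.297. With 1 library left out 3 to 6 mitochondrial members rose and 2 to 4 fell, and without control replicate 2 and cold replicate 5 together 5 peroxisomal members rose and 5 fell.

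Among genes of glucose use, 4 of 24 members of the glycolysis list rose and 1 fell (4 and 1 adjusted over the list alone). Pgam1, a phosphoglycerate mutase, rose by 0.46 and Pfkm, a phosphofructokinase, fell by 0.46. Slc16a1, a lactate and ketone body transporter, was higher by 0.59 (adjusted p = 0.03), a call lost in 6 of the 10 fits without 1 library, with an adjusted p of up to 0.0768. For pyruvate 3 of 15 members rose and 2 fell (3 and 2 adjusted over the list alone). Pcx, pyruvate carboxylase, fell by 0.82 (SE 0.10) and Pdk3, a kinase that inhibits pyruvate dehydrogenase, rose by 1.45 (SE 0.34). Pdk4, of the same kinase family, was higher by 0.69 (adjusted p = 0.0362), a call also lost in 6 of these 10 fits, with an adjusted p of up to 0.0847. For glycogen 2 of 21 members rose and 2 fell (3 and 2 adjusted over the list alone). Pygb, a glycogen phosphorylase, fell by 1.06 (SE 0.09, adjusted p = 1.18e-05) and Gaa, the lysosomal glucosidase, rose by 0.65. The adjusted p of these lists was 0.206, 0.316 and 0.677. In the fits without 1 library 2 to 5 glycolysis members rose (2 without control replicate 4 or cold replicate 1, 2 or 3), and 1 to 4 pyruvate members rose and 1 to 3 fell (1 rose without cold replicate 1, 2 or 3). For glycogen 5 fell without control replicate 2 and cold replicate 5 together.

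Creatine kinase B (Ckb) rose by 2.35 (SE 0.34), from 70.3 ± 34.5 to 359 ± 140 CPM, and Atp2a2, the calcium pump of the endoplasmic reticulum, by 0.65 (SE 0.08). Both belong to the creatine and calcium cycling list, in which 4 of 8 tested members rose and 2 fell, as they did adjusted over the list alone. Gamt, another member, which makes creatine, was lower by 1.06 (adjusted p = 0.0342), a call lost in 7 of the 10 fits without 1 library, with an adjusted p of up to 0.0888. Without cold replicate 1, 2, 3 or 4 no member fell at the threshold (0 of 8), and 1 did without control replicate 1, 2, 4 or 5. For this list camera gave an adjusted p of 0.0777, which was 0.0453 without control replicate 1, 0.0492 without control replicate 4 and 0.0396 without cold replicate 5. It was 0.0465 with the CPM filter and 0.738 with an estimated correlation, and fry gave 0.00445. Acta1, the skeletal muscle actin, chosen after its values were seen, was at 57 CPM in cold replicate 2 and 47.2 in cold replicate 3 against 4.6 to 8.1 in the other 3 cold libraries and 3.7 to 18.2 in the controls (7.93 ± 5.87 CPM in control and 24.5 ± 25.5 CPM in cold libraries, adjusted p = 0.126 in the quasi-likelihood test). The summed skeletal muscle markers were at 76.0 ± 54.4 CPM in control and 213 ± 228 CPM in cold libraries.

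Of 59 nuclear-encoded oxidative phosphorylation genes, which form the respiratory chain and ATP synthase, 14 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.11. Ndufb8 (-0.40), Ndufb3 (-0.44) and Ndufv1 (-0.43), subunits of complex I, and Cox7b (-0.36), a subunit of cytochrome c oxidase, were among them. Without cold replicate 2 or 4, 9 members fell. In the list test the adjusted p was 0.00127, and the adjusted p = 0.797 with an estimated correlation. Tricarboxylic acid cycle genes had 2 members higher and 2 lower of 18 (2 and 3 adjusted over the list alone, list adjusted p = 0.316). Without cold replicate 5, 1 was higher and 5 lower, and in 7 of the other fits without 1 library 1 was higher. Idh3a and Idh2, isocitrate dehydrogenases that use NAD and NADP, were at 0.46 and -0.45. Mitochondrial biogenesis genes had 4 members higher and 0 lower of 29, also adjusted over the list alone (list adjusted p = 0.297); without control replicate 3, 1 was lower. The higher members included Phb (prohibitin, 0.47), Gabpa (a transcription factor of mitochondrial genes, 0.54) and Polrmt (the mitochondrial RNA polymerase, 0.52).

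Of 34 proteasome genes, 18 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.28 and the lowest values in the core subunits Psma5 (-0.69, SE 0.10) and Psmb1 (-0.53, SE 0.08). Without cold replicate 4, 11 fell. Camera gave this list an adjusted p of 1.19e-06, and the adjusted p = 0.797 with an estimated correlation. Of 17 heat shock genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone). Hsph1 rose by 1.36 (SE 0.17), Hspa8 by 1.21 (SE 0.14) and Hsp90aa1 by 0.90 (SE 0.10). This list had an adjusted p of 0.000373, and the adjusted p = 0.708 with an estimated correlation. For the unfolded protein response of the endoplasmic reticulum 4 of 23 members rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.674), and 1 fell without control replicate 4 or cold replicate 1 or 2. The chaperone Calr rose by 0.58, the transcription factor Xbp1 fell by 0.86 and Sdf2l1 rose by 1.59 (adjusted p = 0.0165, and 0.0547 with limma-voom). Among ATF4 targets 1 of 19 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.864). With 1 library left out 0 to 3 rose and 1 to 3 fell, 3 rising without control replicate 1 and 3 falling without control replicate 2. Nupr1, a stress-induced regulator, fell by 0.75, and Slc3a2, an amino acid transporter chain, was higher by 0.82 (adjusted p = 0.0262), a call lost in 5 of the 10 fits without 1 library, with an adjusted p of up to 0.0696.

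Of 36 extracellular matrix genes, 9 rose and 1 fell (13 and 3 adjusted over the list alone), with Loxl1, a collagen and elastin crosslinking enzyme, at 1.48 (SE 0.12, adjusted p = 1.11e-05) and the basement membrane collagen Col4a2 at 0.68. The protease Mmp14 was higher by 0.95 (adjusted p = 0.0243), lost without cold replicate 1, 2 or 4 (adjusted p 0.0571, 0.0562 and 0.068) and with limma-voom (0.0815). Its camera test gave an adjusted p of 0.005, and the adjusted p = 0.797 with an estimated correlation. Of 20 cell cycle genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone). Mki67, a marker of dividing cells, rose by 2.58 (SE 0.53), the topoisomerase Top2a by 2.33 (SE 0.60) and the mitotic kinesin Kif20a by 1.22 (SE 0.29). With limma-voom the adjusted p of Top2a was 0.177. In the list test the adjusted p was 0.0232, and the adjusted p = 0.797 with an estimated correlation. It was 0.0573 without cold replicate 3 and 0.052 without cold replicate 4. Of 20 interferon response genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone), with the antiviral genes Rsad2 at 1.83 (SE 0.38), Ifi44 at 1.93 (SE 0.45) and Ifit2 at 1.35 (SE 0.31). With limma-voom the adjusted p of Ifi44 was 0.0901 and that of Ifit2 0.0532. Camera gave this list an adjusted p of 0.0155, and the adjusted p = 0.797 with an estimated correlation. It was 0.0652 without cold replicate 3 and 0.0579 without cold replicate 4. Cold replicate 5 held 2.06 CPM of Mki67 and 18.9 CPM of Rsad2, against 12.5 to 16.2 and 70.1 to 136.1 in the other 4 cold libraries. Without it 20 matrix, 8 cell cycle and 13 interferon genes rose, and 3 matrix genes fell. Without cold replicate 1 or 4, 4 matrix genes rose, and without control replicate 2, 2 fell. Without control replicate 3 or cold replicate 1, 3 or 4, 5 interferon genes rose, and without control replicate 2 or 5, 6 did. Several marker lists of other cell types were also lower in cold replicate 5 than in the other cold libraries. The median difference on the log2 scale was -0.98 for white adipocytes, -0.69 for Schwann cells and nerve, -0.67 for macrophages and -0.59 for fibroblasts and progenitors. It was smaller for pericytes and smooth muscle (-0.20) and for the endothelium (-0.09). The macrophage marker Cd68 was at 4.5 CPM in cold replicate 5 and at 12.2 to 36.2 in the other cold libraries.

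Angiogenesis signals had 4 members higher and 1 lower of 16 (4 and 2 adjusted over the list alone, list adjusted p = 0.409), and 1 to 5 higher and 1 to 2 lower with 1 library left out (1 higher without cold replicate 1). Apln, the peptide apelin, rose by 1.38 (SE 0.18) and Angpt1, a ligand of the endothelial receptor Tek, fell by 0.97 (SE 0.19). Secreted factors of adipose tissue had 5 members higher and 6 lower of 20 (5 and 8 adjusted over the list alone, list adjusted p = 0.746), with Bmp8b, Fgf21 and Apln higher and Adipoq lower.

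Of 20 tested circadian clock genes 1 rose and 5 fell (3 and 8 adjusted over the list alone). Dbp and Per3, 2 output and feedback genes of the clock, fell by 2.48 (SE 0.46, adjusted p = 0.00286) and 1.54 (SE 0.32, adjusted p = 0.00513). Arntl, the activator at the core of the clock, was higher by 1.47 (SE 0.43, adjusted p = 0.0301) and was chosen after its value was seen. As the 1 member that rose with all libraries, it lost its call in the 7 fits below in which 0 rose. This list had an adjusted p of 0.149, and 0.0396 without cold replicate 5, where 2 members rose and 9 fell. Without control replicate 2 it was 0.451, and 4 rose and 5 fell. Control replicate 3 left out gave 2 and 5, and each of the other 7 libraries left out gave 0 and 5. With a clock score as a covariate, the mean log2 CPM of 7 genes on the Dbp side of the clock minus that of 4 on the Arntl side, an alternative chosen after seeing the data, 167 genes of the transcriptome rose and 101 fell, and 69 of the named genes, Scd1 among them (-0.82, SE 0.27, adjusted p = 0.151), lost their call. Over the 398 genes called at 2-fold or more without this covariate, fold changes kept a median of 0.866 of their size (0.802 over the 286 that lost their call) and the SE grew a median 1.64-fold. Among immediate early genes 3 of 16 rose and 0 fell, also adjusted over the list alone (list adjusted p = 0.283, and 0.0235 without control replicate 2). Dusp1, a MAP kinase phosphatase, rose by 0.96 (SE 0.10) and Cyr61, a matricellular protein, by 0.92 (SE 0.22). Cholesterol synthesis genes had 3 members higher and 1 lower of 22 (2 and 1 adjusted over the list alone, list adjusted p = 0.764), with Pmvk, a kinase of the mevalonate pathway, at -0.89. Of the cholesterol genes 7 were higher and 2 lower without control replicate 1, 2 and 4 without control replicate 2, 1 and 1 without control replicate 4, and 3 and 2 without cold replicate 5.

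**Figure D4:**
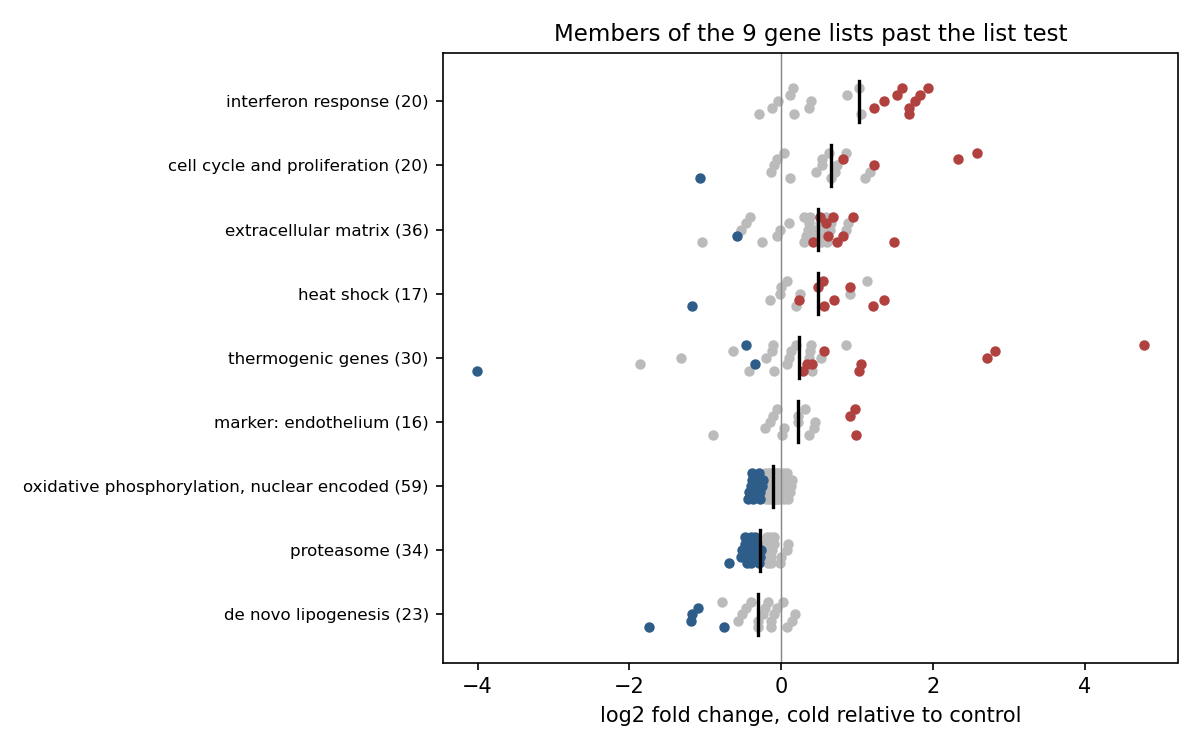
Log2 fold change of cold relative to control (horizontal axis) for each tested member of the 9 lists past the list test with the preset correlation; the number tested is in brackets, red and blue points passed the gene test, grey points did not, and black bars are list medians. The medians run from -0.30 for de novo lipogenesis to 1.03 for the interferon response.

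Markers of other cell types in the dissected tissue were compared as lists. The endothelial list had 3 of 16 members higher and 0 lower, also adjusted over the list alone, with Eng at 0.97 (SE 0.13) and Emcn at 0.98 (SE 0.17). Without control replicate 2, 5 were higher (list adjusted p = 0.0056), and 6 without both that library and cold replicate 5. Its adjusted p was 0.0458, and the adjusted p = 0.797 with an estimated correlation. It lost its call in 5 of the 10 fits without 1 library, those without control replicate 1 (0.18), 3 (0.116) or 5 (0.0998) or cold replicate 1 (0.0584) or 4 (0.0685). Macrophage markers had 3 of 17 members higher and 1 lower, also adjusted over the list alone, with Cd68 at 2.12 (SE 0.46), Lyve1 at 1.21 (SE 0.30) and Itgam at 2.13 (adjusted p = 0.0215). The call of Itgam was lost without control replicate 3 (0.0517) or 4 (0.053) or cold replicate 3 (0.0543) or 4 (0.0614), and its value was 2.78 without control replicate 5. Without cold replicate 5, 5 macrophage markers were higher, and without control replicate 4 or 5 or cold replicate 4 none was lower (0 of 17). With limma-voom the adjusted p was 0.0527 for Cd68 and 0.0631 for Itgam. Fibroblast and progenitor markers had 4 of 12 members higher and 1 lower (5 and 1 adjusted over the list alone), with Ly6a at 0.80 and Cd34 at 0.85 higher and Gsn at -0.65 lower. Without control replicate 3, 4 or 5 or cold replicate 1, 2 or 3, 2 of these were higher. White adipocyte markers had 3 of 11 higher and 0 lower, also adjusted over the list alone, namely Lpgat1 (0.90), Npr3 (1.43) and Nnat (1.83). These last 3 lists had an adjusted p of 0.678, 0.283 and 0.142. Without cold replicate 5 the fibroblast and the white adipocyte list each had an adjusted p of 0.0396.

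Pericyte and smooth muscle markers had 2 of 12 members lower and 0 higher, also adjusted over the list alone (list adjusted p = 0.702). These were Cspg4 at -0.71 and Mcam at -0.59, whose calls were lost in 6 and 5 of the 10 fits without 1 library; 1 member was higher without control replicate 1 or cold replicate 5. The adjusted p of Cspg4 was 0.0592 with limma-voom, and that of Mcam 0.0539 without scaling factors. None of the 6 tested Schwann cell and nerve markers passed the quasi-likelihood test, over all genes or adjusted over the list alone (list adjusted p = 0.715). The closest, Stmn2 and Pmp22, were at 0.74 (adjusted p = 0.0522) and -0.38 (adjusted p = 0.219). Stmn2 passed without control replicate 4 (0.0494) or cold replicate 3 (0.0187), with DESeq2 (0.0464), with the edgeR exact test (0.029) and without scaling factors (0.0493), and Pmp22 was 1 of 3 members that passed, lower, without cold replicate 1 (0.0145). In 4 lists too few members passed the count filter for a list test. Of 3 skeletal muscle markers tested, Actn2 rose by 1.51 (SE 0.36, adjusted p = 0.0116). The 20 untested skeletal muscle markers each had a higher mean in cold than in control libraries, with a wide spread. All markers of that list summed to 76.0 ± 54.4 CPM in control and 213 ± 228 CPM in cold libraries. Kit, the 1 member tested of the neutrophil and mast cell list, was lower by 1.63 (adjusted p = 0.0314), and -0.91 without control replicate 1. Its call was lost without cold replicate 1, 2, 3 or 4 (adjusted p 0.055, 0.0624, 0.0743 and 0.0767) and with limma-voom (0.117). Kit was at 25.3 ± 23.4 CPM in control and 8.14 ± 1.56 CPM in cold libraries. None of the 10 untested members of its list exceeded a mean of 1.12 CPM over all libraries. The fall of Kit alone does not show fewer mast cells. Of 2 erythroid markers Alas2 was higher by 0.95 (adjusted p = 0.0449), a call lost in 7 of the 10 fits and with limma-voom (0.0698). No lymphocyte marker had enough counts, and these markers summed to 8.42 ± 1.26 CPM in control and 7.45 ± 3.87 CPM in cold libraries. In 7 lists, none past the threshold, the median, the mean and the list test differed in sign. These were the cholesterol, ATF4, secreted factor, immediate early, pericyte, macrophage and Schwann cell lists.

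The authors' deposited table of the same comparison listed 11241 genes, 1203 higher and 1020 lower in the cold at an adjusted p under 0.05. Across the 11035 genes in both tables the fold changes had Pearson's r = 0.99998 and Spearman's rho = 0.99998; genes are not independent replicates. Both tables called 1945 genes, each in the same direction. The authors' deposited table alone called 193 of the shared genes and the quasi-likelihood test alone 217.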

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

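The tests of mislabelling, depth and another cell type for control replicate 2, of scaling for the proteasome and respiratory genes, and of clock phase between animals and as the source of all calls were chosen after the result was seen.

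For the 115 named genes and the library totals, 232 groups of 5 libraries were searched for 1 library far from the other 4. Of these 20 had one, where chance gives about 12, and 10 of the 20 were cold replicate 5. In cold replicate 5 the lowest values were Mki67 at 2.06 CPM (12.5 to 16.2 in the other cold libraries), Top2a at 0.374 (7.04 to 9.55), Bmp8b at 32 (68.2 to 83.9), Arhgef37 at 7.67 (18.9 to 26.3), Npr3 at 145 (263 to 322), Nnat at 3.18 (12.5 to 18.8), Sdf2l1 at 1.31 (4.66 to 7.29) and Gamt at 0.748 (1.89 to 2.28). Its high values were Fasn at 27700 CPM (15100 to 18000) and Ndufv1 at 1240 (939 to 1010). Control replicate 2 held the highest Dio2, 1500 CPM (166 to 284 in the other controls), and the lowest Slc25a1 at 610 (1230 to 1550) and Ifit2 at 7.85 (10.8 to 11.8). Control replicate 1 held the lowest Angptl4 at 122 CPM (266 to 291) and no count of Cpne5 (0 CPM against 0.392 to 0.505), and control replicate 3 the highest Lyve1 at 1.84 (0.785 to 0.905). Cold replicate 1 held the highest Pmp22 at 136 CPM (63.2 to 76.9) and the lowest Dusp1 at 67.5 (84.4 to 91.3). Cold replicate 3 held the highest Dio2 at 660 CPM (369 to 425) and the highest Tacr2 at 12.0 (4.49 to 5.75).

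Control replicate 2 stands apart from the other controls on the second principal component. A wrong label is argued against by its median position of 0.128 between the control mean (0) and the cold mean (1), over 429 genes called at 2-fold or more without it that were also tested with all 10 libraries, and depth by its total of 5113051 counts, within the 4446163 to 5776905 of the other controls. RNA of another cell type stays open, since 13 of 16 endothelial markers (median difference from the other controls 0.37 on the log2 scale) and 10 of 12 pericyte and smooth muscle markers (0.27) were higher in it, and erythroid markers summed to 21.4 CPM against 9.95 to 14.7 (log2 ratio to the mean of the other controls 0.77). The median was 0.11 for Schwann cell, -0.21 for fibroblast, -0.29 for white adipocyte and -0.30 for macrophage markers, and the summed skeletal muscle (47.1 CPM), lymphocyte (9.02) and neutrophil and mast cell (9.41) markers did not exceed the highest of the other controls. A response of this animal to something before collection also stays open and is taken up among the other observations.

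Of 34 proteasome genes 18 fell, and of 59 oxidative phosphorylation genes 14 fell. Scaling moves all genes alike, so it cannot set a list apart from the median of all genes, and is argued against for both lists. Their medians lay under that of all genes by a difference of -0.26 to -0.25 (proteasome) and -0.09 (oxidative phosphorylation). That this held with each of the 5 scalings was fixed in advance and adds no support. Under the median of all genes lay 91.2% and 74.6% of members, and 0% and 0.16% of 10000 random lists matched on expression had a median as low. Random lists, here and below, hold unrelated genes and make no allowance for genes that move together. Short counted length is argued against for the proteasome, where 0% of 10000 random lists matched on length and expression had a median as low. It may be enough for oxidative phosphorylation, since 7.34% of such lists had a median as low (list median -0.11, median of the random lists -0.07). A fall of proteasome transcripts with cold stays open as a hypothesis, limited by the adjusted p of 0.797 with an estimated correlation.

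Of 20 clock genes 1 rose and 5 fell, and the labels give no hour of collection. With the group means removed, the Dbp side and the Arntl side of the clock had Pearson's r = -0.68 (permutation p = 0.0333, two-sided, adjusted 0.0333) and Spearman's rho = -0.70 (permutation p = 0.0327, adjusted 0.0333) over 10 libraries, which may reflect different clock phases of the animals at collection (r = -0.45 without cold replicate 5 and control replicate 4, the 2 farthest, so the relation rests in part on them). With the clock score as a covariate 28.1% of the 398 genes called at 2-fold or more stayed past the threshold, 112 genes in number. The score rests on few genes and may measure phase with error, so adjusting for it can leave part of a phase effect in place. The genes that stayed therefore do not exclude clock phase as their source. Clock phase and cold cannot be told apart here, since the score itself differed between the groups (correlation with group -0.79). Over the 398 genes fold changes kept a median of 0.866 of their size and the SE grew a median 1.64-fold. In 214 of the 286 calls that ended the SE grew by a larger factor than the fold change shrank, but not for Scd1 (-1.18, SE 0.20 before and -0.82, SE 0.27 after).

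Chance is argued against for the counts of genes, only to the 1 in 100 that the splits below allow. Every other split mixed cold and control mice, which widens the spread within its groups and can lower its counts. Of 100 splits of the 10 libraries into groups of 5, drawn from 126 and the real one included, 1 split, the real one, gave 2168 or more genes, and the highest of the others gave 236. For genes changed at least 2-fold the real split gave 398, the highest of the others 101, and 1 split reached the real count. Chance is not excluded for the number of lists, where 36 of the 100 splits reached the real 9 and the highest of the others gave 14.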

How the results depend on the processing

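The clock covariate and leaving out control replicate 2 and cold replicate 5 together were chosen after the result was seen. Counts of genes higher (1142) and lower (1026) stayed within 1.5 times under every alternative except the clock covariate, which gave 167 and 101, with 65 and 57 at 2-fold or more; in 214 of the 286 calls lost at 2-fold or more the SE grew by a larger factor than the fold change shrank. The 239 genes higher by 2-fold became 372 with DESeq2, 389 without control replicate 2 and cold replicate 5, and 196 to 374 with 1 library left out (374 without cold replicate 5); the cause was not tested. Testing against a log2 fold change of 1 left 44 higher and 10 lower, by its stricter hypothesis. Lists called higher (5, markers apart) ranged from 3 to 7 with 1 library left out, and the marker lists higher (1) from 0 to 3, and 2 without both libraries. With an estimated correlation 0 lists were higher, 0 lower and 0 marker lists higher (1 of the 31 lists at an unadjusted p under 0.05), and fry gave 0 marker lists (1 at an unadjusted p under 0.05). At the stricter adjusted p under 0.01, 945 genes rather than 1945 were shared with the authors' deposited table. Of the genes in both tables, the authors' alone then called 359 and the quasi-likelihood test alone 47, against 193 and 217 at 0.05. The smaller overlap is therefore not from the threshold alone.

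Same-numbered control and cold libraries deviated with correlations of 0.13, -0.02, -0.07, 0.19 and -0.25, which gave no sign of a pairing by number. Pairs of different number were not compared, so a shared order or batch by number is not excluded. With the replicate block 981 genes rose and 808 fell, 217 and 148 by 2-fold or more; 5 lists were higher and 3 lower.

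Reversed values, none past the threshold with all libraries, were Dio2 at 0.40 (limma-voom), 0.76 (with sample weights), 0.46 (replicate block), 0.58 (surrogate variable), 1.01 (without both libraries) and -0.33 to 0.94 with 1 library left out. Ppargc1a was at 0.48, 0.85, 0.52, 0.61, 0.90 and -0.45 to 1.02 in the same order. With 1 library left out, both turned without control replicate 2 alone; for the other alternatives the cause was not tested. Slc2a1 was at -0.37 with the clock covariate, -0.07 to 0.40 with 1 library left out and 0.42 without both libraries, Slc2a4 at -0.04 without both libraries and 0.01 to 0.15 with 1 left out, Lep at -0.96 to 0.14 and Prdm16 at -0.20 to 0.11 with 1 library left out; the cause was not tested. Of the 103 named genes past the threshold, 15 kept their call under every alternative, 32 with the test against a log2 fold change of 1 set aside and 84 with the clock covariate set aside too. None changed direction. Limma-voom ended 14 of these calls and the test against a log2 fold change of 1 ended 83. The scaling alternatives moved the median log2 fold change of all genes only between -0.028 and 0.013. At this depth 1.5-fold changes were recovered in 42.4% of simulated cases.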

Other observations

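The ketone body list was chosen after the result was seen. The cAMP and glucocorticoid lists were made once control replicate 2 was known to stand apart, before their own members had been looked at.

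Some genes of ketone body metabolism moved in opposite directions. Bdh1 rose by 6.55 on the log2 scale and the monocarboxylate transporter Slc16a1 by 0.59 (a call lost in 6 of the 10 fits without 1 library), while Acat1, a thiolase, fell by 0.29 and another monocarboxylate transporter, Slc16a7, fell by 1.70 (15.2 ± 4.27 to 4.64 ± 0.523 CPM, adjusted p = 0.000131). Oxct1, which activates ketone bodies for use, was at 0.20 (adjusted p = 0.166). Of 8 members tested 2 rose and 3 fell; the list was made after seeing the data.

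Cold replicate 5 differed from the other 4 cold mice in whole groups of genes, while its Ucp1 took 1.74% of counts, against 1.81 to 1.98% in theirs and 0.784 to 0.975% in the controls. All 20 interferon response genes were lower in it, with a median difference of -1.89 on the log2 scale, as were 19 of 20 cell cycle genes (-0.87), 32 of 36 matrix genes (-0.84), 10 of 11 white adipocyte markers (-0.98), 5 of 6 Schwann cell and nerve markers (-0.69), 14 of 17 macrophage markers (-0.67) and 11 of 12 fibroblast and progenitor markers (-0.59). Differences were smaller for pericyte and smooth muscle markers (10 of 12 lower, -0.20) and for endothelial markers (10 of 16 lower, -0.09). All 7 genes of the Dbp side of the clock were higher in cold replicate 5 (1.24). Over 488 genes called at 2-fold or more without it and tested with all 10 libraries, its median position between control (0) and cold (1) was 0.623. The other cold libraries, each over 332 to 398 genes chosen likewise, lay at 0.927 to 1.087. These are values of 1 library, with no test.

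Control replicate 2 carried raised immediate early genes, 14 of 16 above the other controls (median 0.89), besides Dio2 and Ppargc1a. A candidate explanation is an acute cAMP response of that animal, as adrenergic stimulation gives. Of 16 cAMP response genes not looked at before, 14 were higher in it, with a median of 0.67, at percentile 100 of 10000 random lists matched on expression. A glucocorticoid response may also be present, with 12 of 17 target genes higher and a median of 0.27, at percentile 99.5. The random lists held unrelated genes, so a list of genes that vary together could exceed them in any single mouse. The immediate early list also lay at percentile 100, and no other control was scored in this way. These percentiles therefore do not single out either response. The 2 explanations are not exclusive, RNA of other cell types stays open for this library, and handling before collection was not tested. Further groups of genes also differed in control replicate 2. All 4 genes on the Arntl side of the clock were higher in it (median 1.24), and 3 of 7 on the Dbp side (-0.07). Only 1 of 23 de novo lipogenesis genes (-0.94) and 3 of 22 cholesterol genes (-0.71) were higher in it. The cause of these differences was not tested.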
